A study of Homo sapiens with 53 samples.

How the data were processed

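Bulk RNA sequencing was performed on 53 human lymphoma cell lines, with 1 library per line. Per the labels' protocols, the lines were grown in RPMI medium with fetal bovine serum, total RNA was taken from the harvested cells with the MagNA Pure system, and libraries were made with the NEBNext Ultra II RNA kit and run in paired-end mode on a NovaSeq instrument. The authors deposited 1 table of raw, whole-number read counts per gene symbol for all libraries, with no normalization. The submitters' processing notes name bcl2fastq, STAR 2.5.0a, Cufflinks 2.2.1 and the build hg19. The roles of these tools, the counting step, its use of strand and the gene annotation are not given in the sources used here. Each column of the table was matched to its cell line by the library number in the labels, and 0 columns were left unmatched. The labels name no group besides the line, so each line was its own group, and no subtype was assigned to any line.

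The table held 18900 genes and 2 further entries that name no gene. These 2, reads in no annotated feature and ambiguous reads, took 29.1 to 48.2% (median 39.1%) and 0.681 to 1.00% (median 0.905%) of the counts of a library and stayed out of library sizes and tests. XIST and the genes of the Y chromosome, 19 in all, were left out of every step, which left 18881 genes. The counts in genes ranged from 2.42 M in SU_DHL_5 to 43.5 M, with a median of 26.7 M, and the other 52 lines had at least 15.1 M, where M is the unit of counts that CPM is given per. A count of 0 allows a level of up to 3 counts, which is 0.114 CPM in the median library, at most 0.192 CPM in every library but SU_DHL_5, and 1.24 CPM in SU_DHL_5. Where line-specific genes are described, a level given for a single gene in its line carries a 95% exact Poisson interval. Intervals and floors cover counting error only, because reads carry no molecular identifiers here and each line has a single library.

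Library sizes were scaled by the TMM method of edgeR 4.0.16 in R 4.3.3, with factors from 0.91 to 1.089, and log2 CPM was computed with a prior count of 2. The 15062 genes with at least 1 CPM in at least 5 lines were tested. Before the data were examined, 34 gene lists, 30 relations between pairs of measures, the 3 covariates, the rules for naming genes and 53 alternative settings were fixed. A list score is the mean over the list's detected members of the z-scored log2 CPM. Co-variation within a list was the mean pairwise Spearman rho of its members, set against 10000 random lists of the same size matched on mean expression in 20 bins, with a one-sided permutation p adjusted over the 32 lists that had at least 3 tested members. Genes of a list are not replicates, so this p describes these 53 libraries. The immunoglobulin constant list kept 1 of its 15 genes in the table, IGLL5, and the erythroid list kept 0 of 6, so both were not tested. The other genes of these lists were not analysed here.

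Relations across lines were given as Spearman's rho and Pearson's r, each with a two-sided permutation test of 100000 resamples and Benjamini-Hochberg adjustment over the family, and r was computed again without the 2 lines farthest from the median of the first measure. The smallest permutation p these resamples can give is 1e-05, and 10000 random lists can give 0.0001. Of the 30 relations, 28 were run, because IGKC, IGLC2, IGHM and IGHG1 were not analysed here. Where a mixture of 2 Gaussian components (mclust 6.1.1) improved the BIC of a measure by over 10, with Ashman's D over 2 and at least 3 lines in each component, no pooled correlation was given, and r and rho were computed within each cluster of at least 6 lines. With fewer than 10 lines, all orders were enumerated in an exact permutation test. Scores were computed without the other measure's gene and without genes shared with the other list.

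Genes associated with a continuous covariate were found with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) and Benjamini-Hochberg adjustment at 0.05. The covariates were the activated B-cell score minus the germinal centre B-cell score, the log2 CPM of MYC, and the MHC class II score, each scaled to an SD of 1, so that a coefficient is a log2 change per SD. Lines were never divided by a covariate. Gene lists were tested along each covariate with camera (limma 3.58.1) at its preset correlation of 0.01 and again with an estimated correlation, and members past the threshold were counted over all genes tested and adjusted over the list alone. Own members of a covariate were left out. The genes named for a covariate are the 12 with the highest and the 12 with the lowest coefficient among those past the threshold with a mean log2 CPM of at least 2, plus members of the fixed lists. A gene was line-specific where its line had at least 20 CPM and exceeded every other line by at least 3 on the log2 scale, and the gene with the largest gap in a line is named, for up to 20 lines. The 25 most variable genes are named as a list.

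Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for list scores, permutations and plots. The procedures were tested on simulated data. With counts drawn from the means and library sizes of these 53 libraries, edgeR called 73 of 100 genes planted at a log2 change of 1 per SD, 58 of 100 planted at 0.5, and 11 unchanged genes among 142 calls over 15062 genes. The list test recovered 20 of 20 planted lists and called 0 of 20 lists without co-variation. The relation test called 99% of 200 simulated pairs with a true r of 0.6 and 7% of pairs with no relation, before adjustment. Alternatives were RLE in place of TMM, no filter on low counts, DESeq2 1.42.0, limma-voom, Spearman correlation, other gene sets, levels and gaps, lines left out, and total count or library number as a further covariate. Those chosen after seeing the data left out OCI_Ly_7 with OCI_Ly_18, SU_DHL_5 or HLY, or used the share of reads in no feature or the place of the last 7 columns of the table, which stand out of number order, as a covariate. The RefSeq gene table of GRCh38.p14 and GENCODE release 29 served only for gene names, the order of neighbouring genes and the GC content and length of transcripts, because the counts were made on hg19, and no coordinates are printed.

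Genes with near-identical copies, such as HLA, MAGE, histone and ribosomal protein genes, may share reads in ways that cannot be followed in a count table, and antisense genes cannot be told from their partners without the strand. Their values are uncertain in that respect.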

Results

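Gene expression was measured in 53 established human lymphoma cell lines, grown without any treatment named in the labels. The series concerns diffuse large B-cell lymphoma, an aggressive tumour of mature B cells, and its proteogenotypes. Each line contributed 1 library, so differences between lines have no replicate check, and the comparisons run across lines. The libraries held 2.42 to 43.5 M counts in genes (median 26.7 M), and SU_DHL_5, the library with the fewest, lay below the 15.1 M or more of all others. Between 11452 and 13219 genes (median 12220) reached 1 CPM in a line. Levels of MALAT1, an abundant nuclear transcript, took 0.276 to 2.13% of the counts of a library (median 0.675%).

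The most variable genes were abundant in some lines and under 1 CPM in others. IGF2BP1, an RNA-binding protein of fetal and tumour tissue, had the highest SD of log2 CPM (5.50), with at least 100 CPM in 25 lines and under 1 CPM in 22. CD44, an adhesion receptor of the cell surface, followed with an SD of 5.37 and reached 1524 CPM in HBL_1, with 21 lines at 100 CPM or more and 21 under 1 CPM. Genes of the B-cell lineage were among the 25 highest. IGLL1, part of the surrogate light chain of precursor B cells, reached 868.2 CPM in SU_DHL_8 and stayed under 1 CPM in 32 lines. IGLL5, the 1 gene of the immunoglobulin constant list in the table, had a median of 59.1 CPM and was under 1 CPM in 14 lines. TCL1A, an oncoprotein of lymphoid cells, had a median of 258.1 CPM with 34 lines at 100 CPM or more. IRF4, a transcription factor of activated B cells and plasma cells, reached 1959 CPM in HLY and stayed under 1 CPM in 8 lines. CCND2, a cyclin of the G1 phase, was under 1 CPM in 27 lines and at 100 CPM or more in 7. CCL22, a chemokine that attracts T cells, reached 100 CPM in 8 lines and was under 1 CPM in 34. The others were UCHL1, BMP7, MID1IP1, PTPRS, BEST3, GLUL, AMOTL1, VIM, HIST1H3C, BAHCC1, YBX3, CBS, NLRP2, LY6E, SERPINA9, CREB3L2 and BMP3, with SDs between 4.53 and 5.19. Over all 15062 tested genes the median SD was 0.82, with 3397 genes above 2 and 3503 under 0.5.

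Lines that share a name were compared with the other pairs of lines, by Spearman correlation over the 2000 most variable genes. Over the 1378 pairs, rho had a median of 0.330 and ranged from 0.0686 to 0.892. WILL_1 and WILL_2 ranked at place 26 (rho = 0.616). DOGKIT and DOGUM ranked at place 349 (rho = 0.428), and WSU_DLCL and WSU_DLCL_2 at place 813 (rho = 0.303), below the median of all pairs. In the 4 series of names with 4 or more lines (OCI_Ly, SU_DHL, U_29 and WSU), mean rho was 0.377 within a series and 0.345 between lines of different or no series. This difference of 0.0322 was not past the threshold (two-sided permutation p = 0.113). The 3 closest pairs were HBL_1 with OCI_Ly_18 (rho = 0.892), HBL_1 with OCI_Ly_7 (rho = 0.873) and OCI_Ly_7 with OCI_Ly_18 (rho = 0.825), apart from the next pair, GW_93 with DOGKIT (rho = 0.682). HLY had the lowest mean rho with the other lines (0.192).

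**Figure D1:**
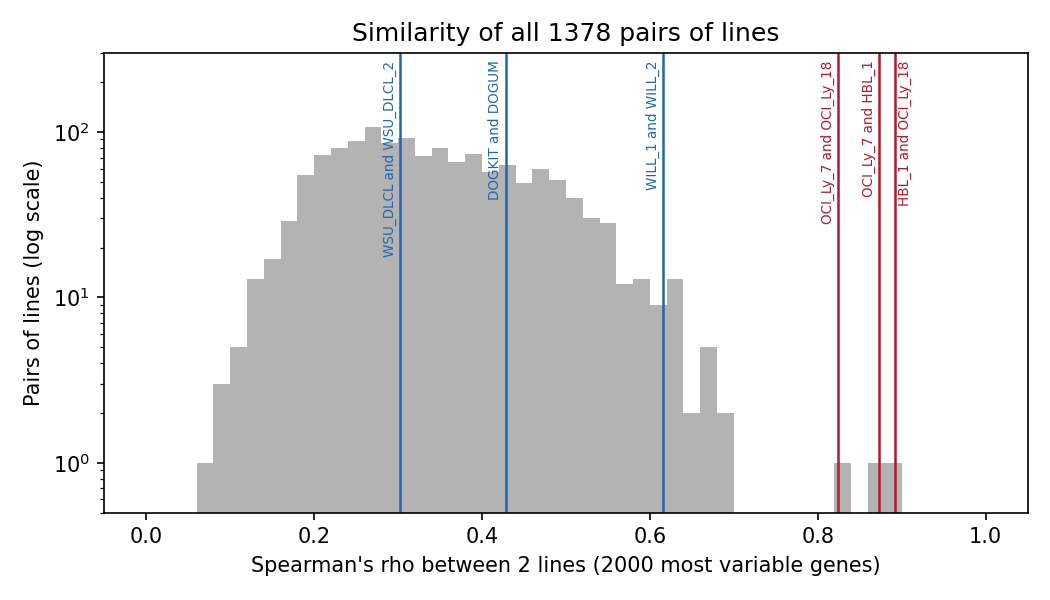
Number of pairs of lines (log scale) by their Spearman rho over the 2000 most variable genes, with 1378 pairs in all. Vertical lines mark the 3 pairs that share a name (blue, rho 0.303 to 0.616) and the 3 pairs among HBL_1, OCI_Ly_7 and OCI_Ly_18 (red, rho 0.825 to 0.892), which lie apart from the rest.

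Genes of most of the fixed lists rose and fell together across the lines. Ribosomal proteins had the highest mean pairwise rho (0.696), followed by MHC class II genes, which present peptides to helper T cells (0.635), and by replication-dependent histones (0.606). The NF-kB targets (0.469), proliferation genes (0.444), MHC class I genes (0.431), MYC targets (0.412), cholesterol synthesis enzymes (0.407), germinal centre B-cell genes (0.392) and activated B-cell genes (0.361) also varied together. Glycolysis had 0.328, the 18q21 segment 0.327, the unfolded protein and amino acid stress genes 0.310, the 9p24 segment 0.308, hypoxia 0.303, the interferon response 0.291, oxidative phosphorylation 0.261 and the primary mediastinal B-cell genes 0.240. Each of these 18 lists had a one-sided permutation p of 0.0001, the smallest that 10000 random lists can give (adjusted p = 0.000168). By the same permutation test, mean rho was 0.410 for the cancer-testis antigens (adjusted p = 0.000556), 0.335 for the 9p21 segment (adjusted p = 0.006), 0.181 for the 2p16 segment (adjusted p = 0.000436), and 0.148 for B-cell identity and 0.144 for B-cell receptor signalling (adjusted p = 0.000305 each). In the permutation test 3 lists passed narrowly, the pro-apoptotic BCL2 family (0.0602, adjusted p = 0.0462), the plasma cell genes (0.0526, adjusted p = 0.0326) and the surface antigens used as drug targets (0.0429, adjusted p = 0.0326). Without HLY the antigens no longer passed this permutation test (0.0369, adjusted p = 0.0533). With Pearson correlation the plasma cell genes (0.0228, adjusted p = 0.176) and the pro-apoptotic family (0.0323, adjusted p = 0.156) did not pass the permutation test, nor did the latter without WILL_2, WSU_DLCL_2 and DOGKIT (0.0537, adjusted p = 0.0578). The permutation test was not past the threshold for the anti-apoptotic BCL2 family (0.0379, adjusted p = 0.273), the chromatin regulators (0.0476, adjusted p = 0.118), or for the markers of T and NK cells (0.0196, adjusted p = 0.777), myeloid cells (0.195, adjusted p = 0.0534) and epithelial and stromal cells (0.121, adjusted p = 0.137). Of the myeloid markers, a permutation p past the threshold was found without SU_DHL_5 (mean rho 0.201, adjusted p = 0.0471) and without HLY (mean rho 0.205, adjusted p = 0.0485). Values are given here for 31 of the 32 lists tested. Histone, HLA, ribosomal protein and cancer-testis genes have near-identical copies, so their values are uncertain. The random lists were matched on expression and not on place, whereas genes of a segment list are neighbours on a chromosome. Neighbours co-varied in general, with a mean rho of 0.248 for adjacent genes and 0.124 for genes 5 apart. The p of a segment list therefore does not show more co-variation than neighbours have elsewhere.

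Cell of origin divides diffuse large B-cell lymphomas into an activated and a germinal centre type, and the lines were placed on a continuous axis from one set of marker genes to the other. PRDM1, the transcription factor that drives plasma cell differentiation, rose by 2.68 per SD of the axis on the log2 scale (SE 0.308, edgeR adjusted p = 9.64e-09) and reached 781.5 CPM in OCI_Ly_3. IRF4 had a median of 474.9 CPM and its highest levels in HLY (1959 CPM) and TMD8 (1923 CPM). MME, the surface peptidase CD10 of germinal centre B cells, had a median of 164.2 CPM and reached 926.2 CPM in WILL_2. It had 0 counts in HBL_1, TMD8, RCK8, SU_DHL_2, U_2940 and OCI_Ly_18, which allows up to 0.0896 CPM in SU_DHL_2 and up to 0.159 CPM in HBL_1. BCL6, the repressor that maintains the germinal centre programme, ranged from 0.882 CPM in WSU_DLCL to 1099 CPM in MIEU. The axis score was highest in OCI_Ly_3, followed by OCI_Ly_18 (2.18), HBL_1 (2.15) and TMD8 (2.12), and ULA (−1.88), HT (−1.87) and SU_DHL_5 (−1.78) had the lowest scores.

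Across the 53 lines the activated B-cell score fell as the germinal centre score rose (rho = −0.481, permutation p = 0.00032, adjusted p = 0.000689; r = −0.544, permutation p = 4e-05, adjusted p = 0.000112). Without OCI_Ly_10 and OCI_Ly_3, the 2 lines farthest from the median, r was −0.504. The activated B-cell score rose with the NF-kB target score (rho = 0.569, permutation p = 2e-05, adjusted p = 7e-05; r = 0.604, permutation p = 1e-05, adjusted p = 4e-05; r = 0.554 without the same lines). It also rose with the plasma cell score (rho = 0.363, permutation p = 0.0077, adjusted p = 0.012; r = 0.343, permutation p = 0.0116, adjusted p = 0.0172; r = 0.391 without the same lines). XBP1, a regulator of secretory capacity, rose with the remaining plasma cell genes (rho = 0.484, permutation p = 0.00026, adjusted p = 0.000607; r = 0.480, permutation p = 0.00026, adjusted p = 0.00056; r = 0.504 without ULA and Farage). TNFAIP3, the feedback inhibitor A20 of NF-kB, rose with the other NF-kB targets (rho = 0.520, permutation p = 8e-05, adjusted p = 0.000224; r = 0.557, permutation p = 4e-05, adjusted p = 0.000112; r = 0.526 without DOHH2 and OCI_Ly_18). These relations and those that follow belong to the 28 that were run.

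**Figure D2:**
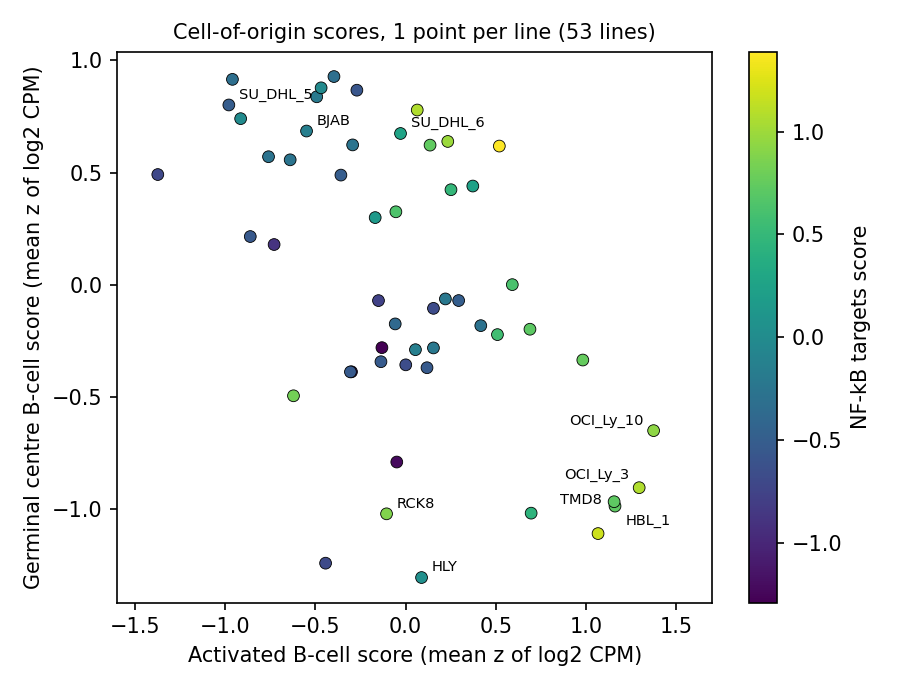
Activated B-cell score against germinal centre B-cell score, each the mean z of log2 CPM over its genes, with 1 point for each of 53 lines coloured by its NF-kB target score. OCI_Ly_10, OCI_Ly_3, TMD8 and HBL_1 lie at the lower right, and the germinal centre score falls as the activated B-cell score rises (rho = −0.481).

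Expression of IRF4, BCL6 and BACH2, transcription factors of the B-cell and plasma cell fates, fell into 2 separate clusters of lines each, so relations were computed within clusters. Among the 37 lines with higher IRF4, PRDM1 rose with IRF4 (rho = 0.405, permutation p = 0.0131, adjusted p = 0.0366; r = 0.464, permutation p = 0.00378, adjusted p = 0.0132; r = 0.624 without OCI_LY_8 and SU_DHL_2). By permutation test this call was lost with total count removed (rho = 0.233, adjusted p = 0.29), without HLY (rho = 0.354, adjusted p = 0.0966) and without OCI_Ly_7 and OCI_Ly_18 (rho = 0.389, adjusted p = 0.0604). In the same lines the germinal centre score fell as IRF4 rose (rho = −0.623, permutation p = 5e-05, adjusted p = 0.000233; r = −0.533, permutation p = 0.00072, adjusted p = 0.00336; r = −0.635 without the same lines). Among the 16 lines with lower IRF4 neither relation was past the threshold in the permutation test, with rho = 0.1 (p = 0.713, adjusted p = 0.832) and r = 0.0333 (p = 0.902, adjusted p = 0.902) for PRDM1. For the germinal centre score rho was −0.224 (permutation p = 0.405, adjusted p = 0.567) and r −0.147 (permutation p = 0.584, adjusted p = 0.753). Without WSU_DLCL_2 and SU_DHL_4, r was −0.0454 and −0.316. PRDM1 fell as BCL6 rose among the 38 lines with higher BCL6 (rho = −0.657 and r = −0.704, permutation p = 1e-05 and adjusted p = 0.00014 for each; r = −0.713 without U_2946 and OCI_Ly_3). In the 15 lines with lower BCL6, rho was −0.0179 (permutation p = 0.955, adjusted p = 0.955) and r −0.112 (permutation p = 0.696, adjusted p = 0.811; r = 0.064 without WSU_DLCL and DOGKIT). For BACH2 and PRDM1 the permutation test was not past the threshold in the 40 lines with higher BACH2 (rho = 0.0141, p = 0.933, adjusted p = 0.955; r = −0.0276, p = 0.865, adjusted p = 0.902; r = 0.189 without OCI_Ly_10 and DOHH2) or in the 13 with lower BACH2 (rho = −0.198, p = 0.514, adjusted p = 0.655; r = −0.288, p = 0.337, adjusted p = 0.525; r = −0.275 without RCK8 and TMD8). Differences between clusters were not tested, and 14 correlations within clusters were computed.

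Along the axis, 2340 of 15062 genes changed by edgeR's quasi-likelihood test, 1361 higher and 979 lower towards the activated end (3607 without the filter on low counts). Besides PRDM1, AHNAK, a very large scaffold protein, rose by 2.53 per SD (SE 0.350), and the NF-kB target CD44 rose by 2.22 (SE 0.524, edgeR adjusted p = 0.00203). KLF2, a factor of lymphocyte trafficking, rose by 1.93 and VDR, the vitamin D receptor, by 1.91. CYFIP1, C1orf186, SLC12A7, KIF21A, DOCK10 and TOX2 rose by 1.71 to 2.16. Without SU_DHL_5, CYFIP1 had a coefficient of 1.97 and was no longer called by edgeR (adjusted p = 0.0817). Of the genes that fell, SLAMF1, a receptor of lymphocyte contacts, had a coefficient of −2.33, CD27, a costimulatory receptor of the TNF receptor family, −2.07 (SE 0.409, edgeR adjusted p = 0.000252) and LCK, a SRC-family kinase, −1.99 (SE 0.344, edgeR adjusted p = 3.21e-05). BTNL9 had −2.54 and the potassium channel gene KCNK12 −2.11, and EEPD1, TRIB2, TTC9, NLRC3, RGCC, GDPD5 and NRGN had −1.89 to −1.64.

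Of the 30 lists tested along the axis, 5 passed camera at its preset correlation. The estimated correlations of these 5 lists were 0.287 to 0.456, so the preset of 0.01 allows for too little co-variation within them. NF-kB targets were higher (camera adjusted p = 0.000593, or adjusted p = 0.638 with an estimated correlation), with 8 of 22 members higher, 0 lower and 8 past when adjusted over the list alone. NFKBIE and NFKBIA, inhibitors that NF-kB induces, rose by 0.83 and 0.48 per SD, NFKBIZ by 0.95, the cytokine subunit EBI3 by 1.23, and TNFAIP3, CFLAR and IER3 rose as well. Proliferation genes were lower (camera adjusted p = 0.000339, or adjusted p = 0.638 with an estimated correlation), with 4 of 20 members lower and 6 past when adjusted over the list alone. CDK1, the kinase of mitotic entry, had a coefficient of −0.30 and the mitotic kinase gene AURKB −0.28, with CCNA2 and CDC20 the other members. Cancer-testis antigens were higher, with 3 of 4 tested members past in both counts (camera adjusted p = 0.0107, or adjusted p = 0.638 with an estimated correlation). These were CTAG2 (4.04), MAGEA1 (3.87) and TEX14 (1.29), with at least 1 CPM in 8, 7 and 22 lines. B-cell identity genes were lower (camera adjusted p = 0.0294, or adjusted p = 0.638 with an estimated correlation), with CD22 (−0.77) and VPREB3 (−1.05) lower, SPIB (0.56) higher and 3 past when adjusted over the list alone. Without HLY this list did not pass (camera adjusted p = 0.187). The primary mediastinal B-cell list passed as higher (camera adjusted p = 0.0379, or adjusted p = 0.638 with an estimated correlation) while its median coefficient was −0.002 and its mean 0.037. Of its members PTPN2 rose by 0.25, 0 passed when adjusted over the list alone, and the call was lost without SU_DHL_5 (camera adjusted p = 0.0527).

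The other 25 lists did not pass (camera adjusted p from 0.0704 to 0.783). Single members of several moved. SLAMF7, a receptor of plasma cells, rose by 1.41, XBP1 by 0.52 and FKBP11 by 0.44 in the plasma cell list. PRDM1 of this list rose as well, while CD27 fell (−2.07), with 5 past when adjusted over the list alone. The demethylase gene TET2 rose by 0.70 and the methyltransferase gene DNMT3A by 0.73 in the chromatin list, where DNMT1 (−0.45), SMARCA4 (−0.29) and MEF2B (−0.63) were lower, with 5 past when adjusted over the list alone. In the 18q21 segment KDSR, VPS4B, PMAIP1 and SEC11C rose by 0.42 to 0.52, with 5 past when adjusted over the list alone. The interferon-induced genes RSAD2 (−2.34) and IFI27 (−1.10) were lower, as was HLA-DOB (−1.18). Markers of other cell types also moved along the axis, with CD8A (4.65), CD7 (2.16), KRT8 (1.32) and COL1A2 (2.41) higher and CD3E (−1.59) and DCN (−1.29) lower. In the T and NK cell list and the epithelial and stromal list, 0 markers had a median of at least 1 CPM. CD8A had 938.2 CPM in Pfeiffer, 11.3 CPM in the next line, RIVA, and a median of 0.0557 CPM over the lines other than Pfeiffer. These coefficients can therefore rest on few lines. Median and test differed in sign for B-cell receptor signalling, surface antigens and unfolded protein stress, and mean and test for the interferon response, B-cell receptor signalling, surface antigens and ribosomal proteins.

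MYC, the transcription factor of cell growth that is often rearranged in these lymphomas, ranged from 5.60 log2 CPM in SU_DHL_5 and 6.09 in HT to 10.01 in OCI_Ly_19 and 10.72 in MIEU. NOLC1 and NCL, nucleolar proteins, rose with it by 0.36 (SE 0.061, edgeR adjusted p = 0.000409) and 0.27 per SD of MYC, and POLR1B, a subunit of RNA polymerase I, by 0.38 (SE 0.062, edgeR adjusted p = 0.000271). The score of the MYC targets rose with MYC across the lines (rho = 0.724 and r = 0.702, permutation p = 1e-05 and adjusted p = 4e-05 for each; r = 0.638 without SU_DHL_5 and HT). The proliferation score did not pass the permutation test with MYC (rho = 0.0413, p = 0.769, adjusted p = 0.769; r = −0.000456, p = 0.997, adjusted p = 0.997; r = 0.0167 without the same lines).

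**Figure D3:**
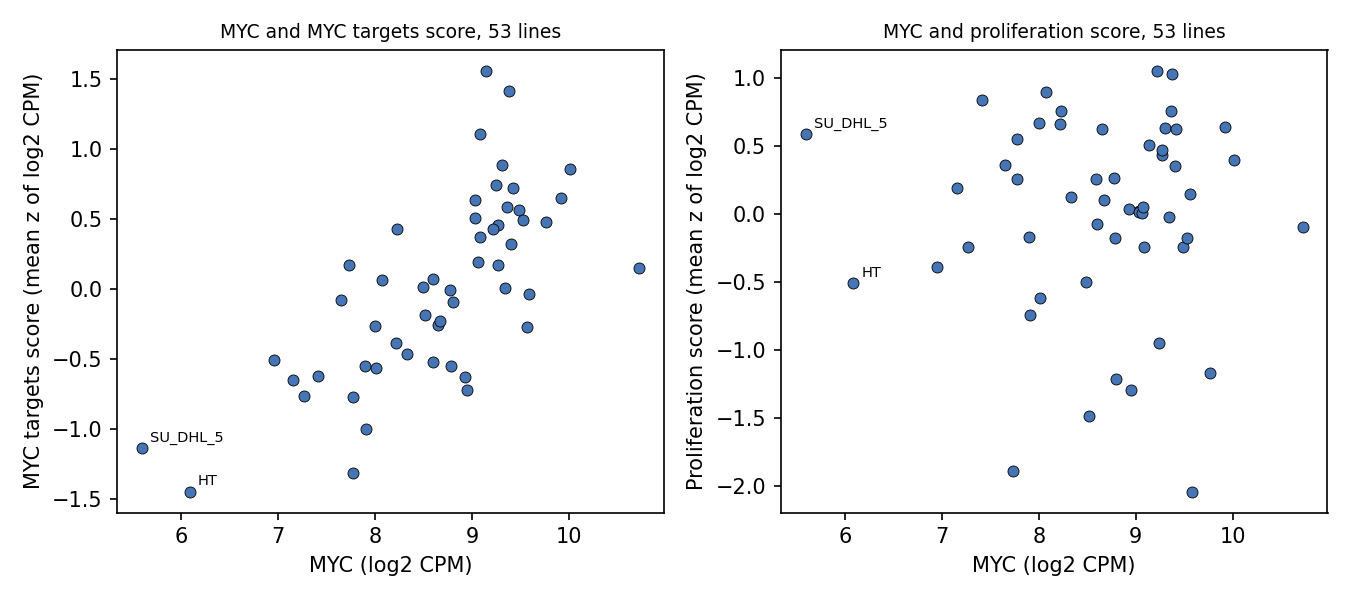
MYC (log2 CPM) against the MYC target score (left, rho = 0.724) and the proliferation score (right, rho = 0.0413), each score the mean z of log2 CPM, with 1 point for each of 53 lines. SU_DHL_5 and HT have the lowest MYC.

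The MYC target score showed no relation past the threshold with proliferation (rho = 0.221, permutation p = 0.11, adjusted p = 0.134; r = 0.190, permutation p = 0.172, adjusted p = 0.193; r = 0.144 without SU_DHL_8 and HT). The same held for oxidative phosphorylation (rho = −0.0793, permutation p = 0.57, adjusted p = 0.591; r = 0.0488, permutation p = 0.729, adjusted p = 0.756; r = −0.0234 without the same lines). EZH2, the histone H3 lysine methyltransferase, rose with proliferation (rho = 0.536, permutation p = 4e-05, adjusted p = 0.000124; r = 0.597, permutation p = 2e-05, adjusted p = 7e-05; r = 0.503 without HLY and OCI_LY_8).

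By edgeR, 463 genes changed with MYC, 279 higher and 184 lower. The count was 221 with limma-voom, 271 without WILL_2, WSU_DLCL_2 and DOGKIT, 294 without the 2 farthest lines, 295 with library number as a covariate, 878 without the filter on low counts and 1062 with DESeq2. TFAP4, a transcription factor induced by MYC, rose by 0.65 per SD (SE 0.084, edgeR adjusted p = 2.94e-06), TERT, the catalytic subunit of telomerase, by 0.64 (SE 0.185, edgeR adjusted p = 0.0415) and UCK2, an enzyme of pyrimidine salvage, by 0.46 (SE 0.105). NXN (1.42) and FHIT (1.01) rose as well. STARD9, FLJ42627, VPS9D1-AS1, FBRSL1, LOC90784, SH3YL1 and ZFP36L2 rose by 0.46 to 0.64, with the antisense gene VPS9D1-AS1 uncertain. Among the genes that fell, UPP1, a uridine phosphorylase, had a coefficient of −1.36 (SE 0.253, edgeR adjusted p = 0.00131) and STAT3, a transcription factor of cytokine signalling, −0.61 (SE 0.178, edgeR adjusted p = 0.0469). KCNIP2 (−1.07), BZRAP1 (−0.92), FCRLB (−0.83), ADPRHL1, SLC12A4, CCPG1, NQO2, the macrophage marker CD68 (−0.58) and the autophagy receptor gene SQSTM1 (−0.57) were lower as well. Without SU_DHL_5, 6 of these genes were no longer called by edgeR, namely SH3YL1 (0.541, adjusted p = 0.0646), ZFP36L2 (0.487, adjusted p = 0.0608), FCRLB (−0.768, adjusted p = 0.0786), CCPG1 (−0.48, adjusted p = 0.0659), CD68 (−0.532, adjusted p = 0.098; −0.599, adjusted p = 0.0537 without OCI_Ly_7 and OCI_Ly_18) and SQSTM1 (−0.491, adjusted p = 0.0853). Other settings ended more of the calls named by the rule for MYC. These were 12 by limma-voom, 11 without the 2 farthest lines and 8 without WILL_2, WSU_DLCL_2 and DOGKIT. Spearman correlation and library number as a covariate ended 7 each.

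Of 32 lists, 4 passed camera along MYC at the preset correlation of 0.01, which lay below their estimated correlations of 0.163 to 0.435. The MYC targets were higher, with 14 of 22 members past over all genes and 19 when adjusted over the list alone (median 0.27, camera adjusted p = 2.23e-23). This was the 1 call that held with an estimated correlation, with an adjusted p = 0.00138 with an estimated correlation. MYBBP1A, DKC1 and NOP56 were among the members that rose, by 0.39, 0.32 and 0.28. The other 3 lists were lower. NF-kB targets passed (camera adjusted p = 0.0135, or adjusted p = 0.801 with an estimated correlation) with 0 of 22 members past in either count. Unfolded protein and amino acid stress genes passed (camera adjusted p = 0.0135, or adjusted p = 0.801 with an estimated correlation) with 1 member lower in both counts, DDIT3, the stress factor CHOP (−0.46). B-cell receptor signalling genes passed (camera adjusted p = 0.034, or adjusted p = 0.801 with an estimated correlation) with 1 member lower in both counts, the adaptor gene GRB2 (−0.30). Without SU_DHL_5 the stress list was lost (camera adjusted p = 0.114) and 7 lists passed in all at the preset correlation, and without HLY the B-cell receptor list was lost (camera adjusted p = 0.0556). The other 28 lists did not pass (camera adjusted p from 0.0785 to 0.99), with CYCS of the oxidative phosphorylation list higher (0.28). Among these, the test differed in sign from both median and mean for activated B-cell genes, MHC class I, primary mediastinal B-cell genes and the 18q21 segment. It differed from the median alone for oxidative phosphorylation, anti-apoptotic and T and NK cell genes, and from the mean alone for MHC class II, proliferation, hypoxia, surface antigens and the 9p24 segment.

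MHC class II molecules present peptides to CD4 T cells, and their genes were low in a few lines. HLA-DRA had a median of 664.5 CPM and was highest in SKI_DLCL_1 (1498 CPM), while OCI_Ly_1 and OCI_Ly_10 had 0 counts, which allows up to 0.0968 and 0.128 CPM. The invariant chain gene CD74 had a median of 1435 CPM and its lowest level of 190.9 CPM in SU_DHL_2. The class II score was lowest in OCI_Ly_1 (−2.47), SU_DHL_2 (−2.21), SU_DHL_16 (−1.65), WSU_DLCL (−1.54) and OCI_Ly_10 (−1.37). For MHC class I, OCI_Ly_10 (−2.14) and DB (−1.96) had the lowest scores, DB with 0.606 CPM of HLA-E and 2.18 CPM of HLA-C. B2M, the light chain of class I molecules, ranged from 121.0 CPM in OCI_Ly_1 to 1272 CPM in HLY. HLA genes have near-identical copies, so their levels are uncertain.

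CIITA, the master activator of class II genes, fell into 2 separate clusters. The 7 lines with lower CIITA were DB, HT, Karpas_1106_P, OCI_Ly_1, SU_DHL_2, SU_DHL_16 and WSU_DLCL. Their class II scores lay between −2.47 and −0.261, and the 4 lowest scores of all lines were among them, but the difference between the clusters was not tested. CIITA and the class II score were not related past the threshold within them (rho = 0.393, exact permutation p = 0.396, adjusted p = 0.567; r = 0.234, exact permutation p = 0.592, adjusted p = 0.753; r = −0.321 without HT and SU_DHL_16). The same held within the other 46 lines (rho = 0.192, permutation p = 0.199, adjusted p = 0.398; r = 0.257, permutation p = 0.085, adjusted p = 0.198; r = 0.0959 without SKI_DLCL_1 and RIVA). In these 46 lines the relation passed the permutation test with the share of reads in no feature removed (rho = 0.393, adjusted p = 0.0207). NLRC5, the activator of class I genes, had 6 lines with lower levels, WSU_DLCL_2, HT, OCI_Ly_1, SU_DHL_6, SU_DHL_16 and ULA. Within these the relation with the class I score was not past the threshold (rho = 0.657, exact permutation p = 0.175, adjusted p = 0.398; r = 0.474, exact permutation p = 0.325, adjusted p = 0.525; r = 0.903 without SU_DHL_16 and SU_DHL_6). Among the other 47 lines the class I score rose with NLRC5 (rho = 0.598, permutation p = 2e-05, adjusted p = 0.00014; r = 0.490, permutation p = 0.00047, adjusted p = 0.00329; r = 0.391 without DB and RL). The class I and class II scores were not related past the threshold (rho = 0.0969, permutation p = 0.487, adjusted p = 0.525; r = 0.264, permutation p = 0.0545, adjusted p = 0.0636). Without OCI_Ly_10 and DB, r was 0.0979.

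**Figure D4:**
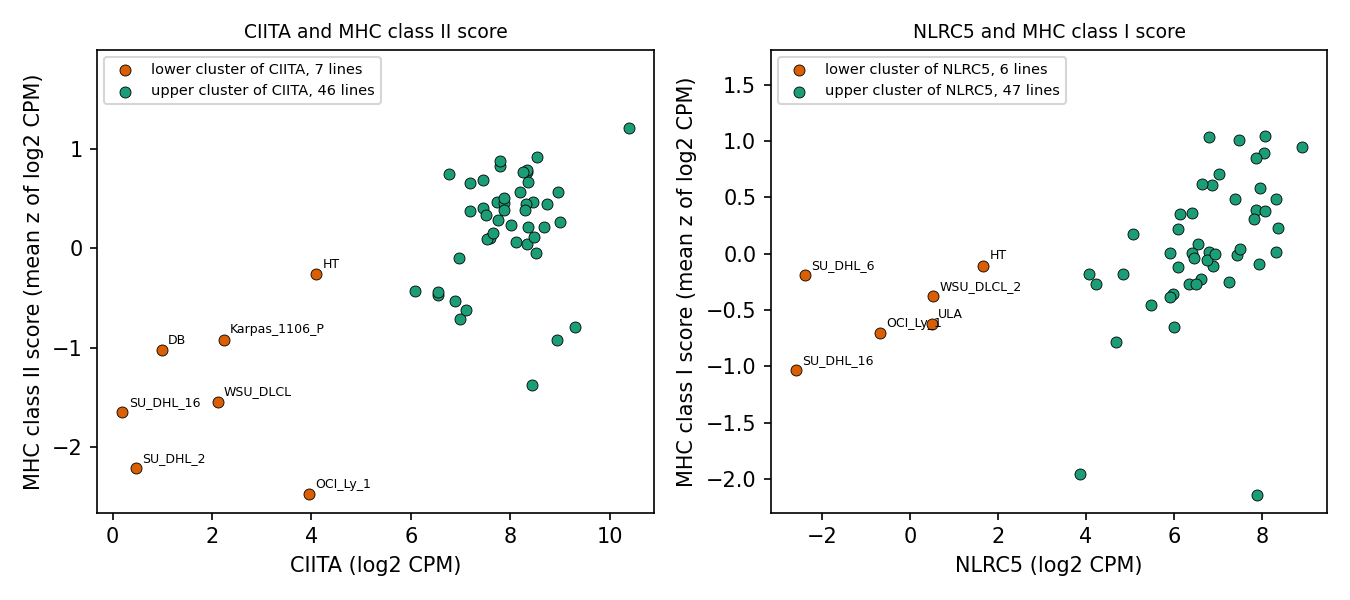
CIITA (log2 CPM) against the MHC class II score (left) and NLRC5 (log2 CPM) against the MHC class I score (right), each score the mean z of log2 CPM, with 1 point for each of 53 lines. The lines of the lower clusters (7 for CIITA, 6 for NLRC5) are orange and named, and the other 46 and 47 lines are green.

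With the class II score, 149 genes changed by edgeR, 34 higher and 115 lower. The count was 44 with limma-voom, 328 without the 2 farthest lines, OCI_Ly_1 and SU_DHL_2, 674 with DESeq2 and 874 without the filter on low counts. Of the 149 genes, 20 were among the 44 of limma-voom and 25 among the 117 called by Spearman correlation. INSR, the insulin receptor, rose by 2.38 per SD (SE 0.613, edgeR adjusted p = 0.0334), DEPTOR, an inhibitor of mTOR, by 1.84 (SE 0.432, edgeR adjusted p = 0.0164) and GNG7, a G protein subunit, by 1.58. LHFP, MIR600HG, RRP7BP, TNRC18, GIT2, SF3A2, RPS18, CIZ1 and FNBP4 rose by 0.17 to 1.57. RPS18 lies among the ribosomal proteins with near-identical copies and is uncertain. FNBP4 was no longer called by edgeR without HLY (0.171, adjusted p = 0.056) or without SU_DHL_5 (0.168, adjusted p = 0.0563), and GNG7 without OCI_Ly_7 and OCI_Ly_18 (adjusted p = 0.0596). Among the genes that fell, TRIB1, a pseudokinase, had a coefficient of −1.03, NQO1, a quinone reductase, −0.63 (SE 0.145, edgeR adjusted p = 0.0124) and MAP3K14, the kinase NIK of the alternative NF-kB pathway, −0.49 (SE 0.119, edgeR adjusted p = 0.0235). KCNIP2, PBX3, RAB27A, RAP2A, KAT6B, ZFAT and WDR44 had −0.86 to −0.39. Their Spearman rho with the score ranged from −0.586 for WDR44 to −0.112 for KAT6B, so some of these genes had little relation in rank. PBX3 was not called by edgeR without SU_DHL_5 (−0.736, adjusted p = 0.0513). FBXO32, a ubiquitin ligase subunit, had the lowest coefficient among called genes with a mean log2 CPM of at least 2 (−1.89), which rested on HLY. Without that line FBXO32 was at −0.539 (edgeR adjusted p = 0.36).

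Of 31 lists, 9 passed camera along the class II score, and none held with an estimated correlation. The estimates for these 9 lists ran from 0.0195 for chromatin regulators to 0.679 for ribosomal proteins. They lay above the preset of 0.01, so the preset p allows for too little co-variation within a list. Ribosomal proteins were higher (median 0.10, camera adjusted p = 1.39e-11), with 0 of 25 members past over all genes and 11 when adjusted over the list alone (adjusted p = 0.535 with an estimated correlation). MYC targets (camera adjusted p = 0.00423, or adjusted p = 0.547 with an estimated correlation) and germinal centre genes (camera adjusted p = 0.00564, or adjusted p = 0.547 with an estimated correlation) were higher. So were MHC class I genes (camera adjusted p = 0.00564, or adjusted p = 0.535 with an estimated correlation), though with a median of 0.01 and a mean of 0.002. Chromatin regulators were higher too (camera adjusted p = 0.00704, or adjusted p = 0.133 with an estimated correlation). In these 4 lists 0 members passed in either count. NF-kB targets were lower (median −0.39, camera adjusted p = 8.93e-05), with 0 of 22 past over all genes and 3 when adjusted over the list alone (adjusted p = 0.535 with an estimated correlation). Primary mediastinal B-cell genes were lower (camera adjusted p = 0.0273), with 2 of 14 past over all genes and 8 when adjusted over the list alone (adjusted p = 0.547 with an estimated correlation). These 2 were FCER2, the IgE receptor CD23 (−2.71), and TNFRSF8, the surface antigen CD30. Cancer-testis antigens were lower (camera adjusted p = 0.00465, or adjusted p = 0.448 with an estimated correlation) with 1 member past in both counts, MAGEA1 (−4.42). The 9p24 segment was lower (camera adjusted p = 0.00729, or adjusted p = 0.535 with an estimated correlation), with 0 members past over all genes and 1 when adjusted over the list alone. Of the other 22 lists, with camera adjusted p from 0.122 to 0.999, the epithelial and stromal list held 1 member past the threshold, LUM (−2.25), and the surface antigens held TNFRSF8. The test differed in sign from the mean for plasma cell and B-cell identity genes, and from both median and mean for unfolded protein stress.

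Of the 21 interferon response genes, 13 had a median of at least 1 CPM. ISG15, a ubiquitin-like protein, had a median of 14.6 CPM and reached 668.9 CPM in RCK8, and MX1, an antiviral GTPase, reached 652.2 CPM in Karpas_1106_P. Cholesterol synthesis enzymes were high in HT, with 743.2 CPM of FDFT1, the squalene synthase. SREBF2, the sterol-regulated factor of the pathway, rose with the cholesterol score (rho = 0.416, permutation p = 0.00222, adjusted p = 0.00388; r = 0.466, permutation p = 0.0005, adjusted p = 0.001; r = 0.345 without Farage and HT). CDKN1A, a cell cycle inhibitor, and MDM2, a ubiquitin ligase, rose together (rho = 0.327, permutation p = 0.0172, adjusted p = 0.0253; r = 0.305, permutation p = 0.0265, adjusted p = 0.0372; r = 0.394 without DB and U_2946). This call was lost without HLY (rho = 0.288, permutation test, adjusted p = 0.0564), the line with the highest MDM2 (1225 CPM).

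Neighbouring genes of segments that are often gained or lost in lymphoma were compared next. Neighbours co-varied in general, so the permutation tests of 2 genes of a segment do not show a relation beyond that of neighbours elsewhere. CD274 and PDCD1LG2, the PD-1 ligands on 9p24, rose together (rho = 0.705 and r = 0.667, permutation p = 1e-05 and adjusted p = 4e-05 for each; r = 0.599 without Karpas_1106_P and Med_B1). CD274 reached 148.9 CPM in Karpas_1106_P against a median of 1.19 CPM, and PDCD1LG2 195.8 CPM in ULA. CD274 also rose with JAK2, a cytokine receptor kinase of the same segment (rho = 0.451, permutation p = 0.00079, adjusted p = 0.00158; r = 0.495, permutation p = 0.00015, adjusted p = 0.000382; r = 0.405 without the same lines). On 18q21, BCL2, an inhibitor of apoptosis, rose with KDSR, a sphingolipid enzyme (rho = 0.405, permutation p = 0.00299, adjusted p = 0.00492; r = 0.438, permutation p = 0.00227, adjusted p = 0.00374; r = 0.520 without HT and SU_DHL_10). BCL2 was not related past the threshold to MALT1, a protease of NF-kB signalling (rho = 0.226, permutation p = 0.103, adjusted p = 0.131; r = 0.281, permutation p = 0.0415, adjusted p = 0.0505; r = 0.327 without the same lines). Neither was it to its relative MCL1 (rho = −0.276, permutation p = 0.0448, adjusted p = 0.0597; r = −0.286, permutation p = 0.0388, adjusted p = 0.0505; r = −0.223 without the same lines). On 2p16, the NF-kB subunit gene REL and the nuclear export gene XPO1 showed no relation past the threshold (rho = −0.102, permutation p = 0.468, adjusted p = 0.524; r = −0.0967, permutation p = 0.492, adjusted p = 0.53; r = −0.166 without Pfeiffer and SU_DHL_8).

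**Figure D5:**
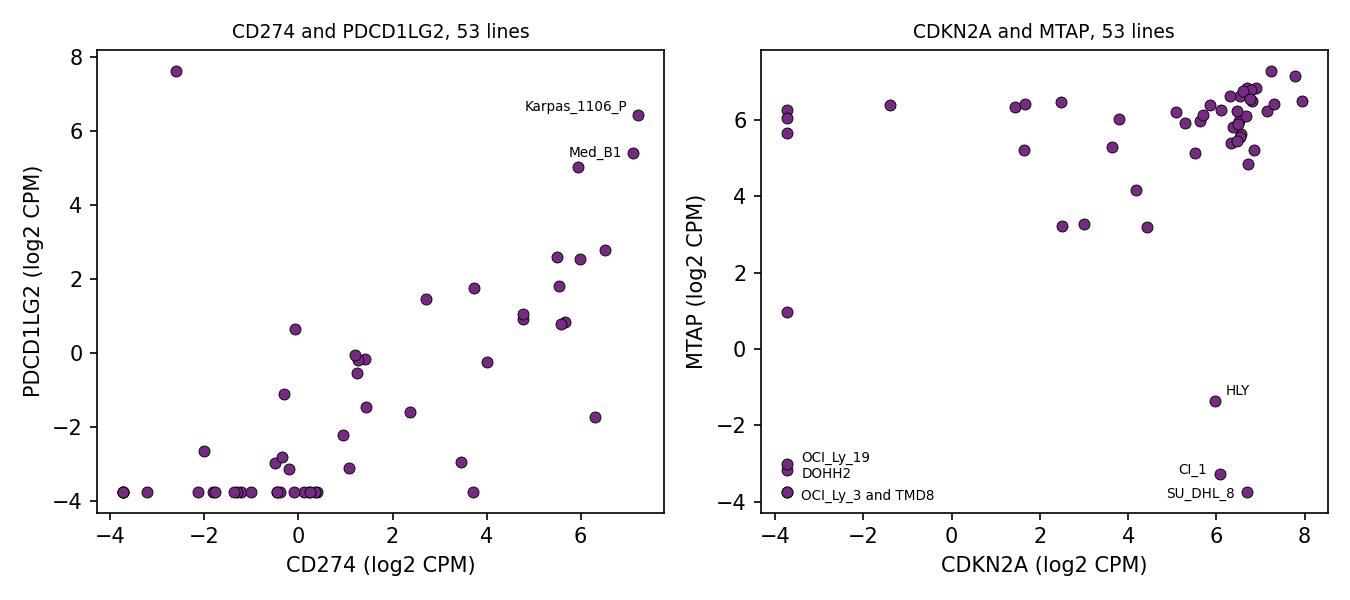
CD274 against PDCD1LG2 (left, rho = 0.705) and CDKN2A against MTAP (right), all in log2 CPM, with 1 point for each of 53 lines. OCI_Ly_3, TMD8, DOHH2 and OCI_Ly_19 lie at the lower left of the right panel, under 1 CPM for both genes.

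CDKN2A, which encodes cell cycle inhibitors, and its 9p21 neighbour MTAP, an enzyme of methionine salvage, had medians of 67.2 and 62.4 CPM. CDKN2A was under 1 CPM in 9 lines and MTAP in 7, and 4 lines, OCI_Ly_3, TMD8, DOHH2 and OCI_Ly_19, were under 1 CPM for both. By chance 1.19 lines would be (one-sided permutation p = 0.0118). Both genes fell into separate clusters, so no correlation over all lines is given. Among the 33 lines with higher CDKN2A, MTAP rose with it in rank (rho = 0.466, permutation p = 0.00697, adjusted p = 0.0244) but not past the threshold by Pearson's r (r = 0.226, permutation p = 0.207, adjusted p = 0.414; r = 0.252 without WSU_DLCL and Farage). In the 20 lines with lower CDKN2A, neither passed after adjustment (rho = 0.268, permutation p = 0.252, adjusted p = 0.441; r = 0.518, permutation p = 0.0203, adjusted p = 0.057; r = 0.388 without OCI_Ly_3 and TMD8).

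Line-specific genes, at 20 CPM or more and at least 3 on the log2 scale above every other line, numbered 231 in 42 lines, with a median of 2 genes per line. The number was 486 with a gap of 2, 127 with a gap of 4, 378 from 5 CPM and 141 from 50 CPM. HBL_1 had 0, while 10 genes met the rule there against the 50 lines other than OCI_Ly_7 and OCI_Ly_18. HLY had the most (43), followed by WSU_DLCL (22), RCK8 (15) and Pfeiffer (13). POSTN, a secreted matrix protein, reached 414.6 CPM in Karpas_1106_P (95% exact Poisson interval 407.2 to 422.2 CPM), where the next line, DOGUM, had 0.327 CPM. MUC21, a mucin of epithelia, reached 143.3 CPM in SKI_DLCL_1 (interval 139.0 to 147.8 CPM) against 0.209 CPM in HLY. GPR25, an orphan receptor, reached 165.9 CPM in HLY (161.3 to 170.7 CPM), CAPN13, a calpain protease, 196.8 CPM in HT (191.7 to 202.0 CPM) and CD8A, the co-receptor of cytotoxic T cells, 938.2 CPM in Pfeiffer (928.1 to 948.5 CPM). CDH1, the adhesion protein E-cadherin of epithelia, reached 177.4 CPM in TMD8 (172.2 to 182.8 CPM) against 2.02 CPM in RIVA, and SLC7A2, a transporter of cationic amino acids, 221.4 CPM in OCI_Ly_7 (214.0 to 228.9 CPM) against 2.91 CPM in HBL_1. Large gaps were also found for SLC24A3 in WSU_DLCL, CYTL1 in OCI_Ly_19, CMKLR1 in OCI_Ly_10, ADRA1B in OCI_Ly_3 and SLC6A15 in MIEU, with 32.1 to 92.6 CPM in the line and under 0.7 CPM in the next.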

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

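Most results kept their side of the threshold, and those past it also their direction. This held in 893 of 1032 repeats for the named genes (137 weaker, 2 reversed) and 186 of 189 for relations across all lines. Within clusters it held in 121 of 125, and for co-variation of lists in 248 of 256. For relations and lists not past the threshold, a change of sign was not counted. The class I and class II scores, for example, had a rho of 0.0969, and of −0.000905 without OCI_Ly_10 and DB. Named genes of the class II score depended most on the test, with 9 of 24 the same by limma-voom (14 weaker) and 13 by Spearman correlation (10 weaker), and of 24 for MYC 12 were weaker by limma-voom. For the class II score, 9 were also weaker with the share of reads in no feature as a covariate and 8 with total count. Leaving out the 2 farthest lines made 8 weaker. Leaving out WILL_2, WSU_DLCL_2 and DOGKIT, or adding the last 7 columns as a covariate, made 5 weaker each. The cause of the changes below was not tested. Without the filter on low counts, 3607 genes passed for the cell-of-origin axis, 878 for MYC and 874 for the MHC class II score. DESeq2 gave 1062 genes for MYC and 674 for the class II score, and limma-voom gave 221 and 44. Without the 2 farthest lines they were 294 and 328. MYC had 271 genes without WILL_2, WSU_DLCL_2 and DOGKIT, and 295 with library number as a further covariate. FBXO32 turned from lower to 0.015 with limma-voom and to a Spearman rho of 0.0462. With an estimated correlation, 0 lists passed camera for the axis, 1 for MYC and 0 for the class II score, and 7 passed for MYC without SU_DHL_5 at the preset correlation. Without WILL_2, WSU_DLCL_2 and DOGKIT, rho was 0.283 for CDKN1A and MDM2 (not past the threshold) and −0.299 for BCL2 and MCL1 (past the threshold), and the pro-apoptotic list had a mean rho of 0.0537 (not past). Without HLY, rho was 0.288 for CDKN1A and MDM2 and 0.354 for IRF4 and PRDM1 in the upper cluster, and the surface antigens had a mean rho of 0.0369, all not past. IRF4 and PRDM1 were also not past at 0.233 with total count removed and 0.389 without OCI_Ly_7 and OCI_Ly_18. CIITA and the class II score passed in the upper cluster with the share of reads in no feature removed (0.393). By Pearson correlation the plasma cell list (0.0228) and the pro-apoptotic list (0.0323) did not pass. The myeloid markers passed with total count removed (0.207) and without OCI_Ly_7 and OCI_Ly_18 (0.199), SU_DHL_5 (0.201) or HLY (0.205). Line-specific genes numbered 486 with a gap of 2, 127 with a gap of 4, 378 from 5 CPM and 141 from 50 CPM. Alternatives that left out OCI_Ly_7 with OCI_Ly_18, SU_DHL_5 or HLY, or used the share of reads in no feature, were chosen after seeing the data. Cluster as a further factor was not run, because no covariate fell into separate clusters. No paired analysis was possible because each line has 1 library and is its own group. Depth limits SU_DHL_5 most, where 0 counts allow up to 1.24 CPM.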

Other observations

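The levels in these paragraphs were picked out for their size, and OCI_Ly_10's region was chosen after its values were seen. In OCI_Ly_10 every gene of the table from HLA-DRA to LOC100294145 in the order of the reference had 0 counts, which allows up to 0.128 CPM. These 15 genes include HLA-DRB1, HLA-DQA1 and HLA-DQB1, which form class II molecules, TAP1 and TAP2, which carry peptides to class I molecules, and PSMB8 and PSMB9, subunits of the immunoproteasome. Their medians over all lines were 665 CPM for HLA-DRA, 146 CPM for HLA-DRB1, 87.0 CPM for TAP1, 160 CPM for TAP2, 73.9 CPM for PSMB8 and 50.1 CPM for PSMB9. The neighbours HLA-DMB (91.9 CPM), HLA-DMA (146 CPM), HLA-DOA (82.6 CPM), HLA-DPA1 (406 CPM) and HLA-DPB1 (118 CPM) were detected in the same library. OCI_Ly_10 was the 1 line at 0 for TAP1, TAP2, PSMB8 and PSMB9. HLA genes have near-identical copies and their values are uncertain.

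Other genes stood high or absent in single lines. Pfeiffer had the highest levels of 7 genes of the 2p16 segment, among them the NF-kB subunit gene REL (2098 CPM) and the ubiquitin protease gene USP34 (2094 CPM). U_2932 was highest for 6 genes of the 18q21 segment, with 420.8 CPM of KDSR and 548.3 CPM of PMAIP1, which promotes apoptosis. ROR1, a surface receptor used as a drug target, reached 248.9 CPM in WILL_1, 248.5 CPM in DOGKIT and 222.7 CPM in WILL_2 and was under 1 CPM in 32 lines. BCL2 ranged from 0.452 CPM in HT to 2598 CPM in SC_1. CD22, a surface antigen of B cells, had a median of 404 CPM and 0 counts in RCK8 (up to 0.139 CPM).

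All tests below were chosen after the result was seen, as were the bounds that decide them. The libraries labelled HBL_1, OCI_Ly_7 and OCI_Ly_18 were closer to one another by Spearman's rho than any other pair, and no biological explanation was tested for this pattern. They were not 1 library under several names, since the counts of HBL_1 and OCI_Ly_7 differed by a chi-square of 59 per degree of freedom, where 1 is due for a single library, and the other 2 pairs by 149 and 111, above the lowest pair outside the 3 (92.2). For libraries that differ, this value grows with the number of counts, so it does not rank pairs of unlike depth by closeness. The same cells cultured under different names could account for HBL_1 and OCI_Ly_18, because 23 genes were on (at least 20 CPM) in one and off (under 1 CPM) in the other, against 96 or more in every pair outside the 3. HBL_1 and OCI_Ly_7 had 19 such genes and OCI_Ly_7 and OCI_Ly_18 had 42, so this count does not set HBL_1 and OCI_Ly_18 apart from them. For OCI_Ly_7, 18 genes were on there and off in HBL_1, among them MME (25.5 CPM) and TCL1A (85.6 CPM), against 1 the other way (exact binomial p = 7.63e-05). Genes are not replicates and each line has 1 library, so this p does not measure variation between cultures. Other cells mixed into either library stay open, although of 8032 genes at 20 CPM or more in HBL_1, 17 were under 10% of that level in OCI_Ly_7 and 35 in OCI_Ly_18, where a mixture keeps the share of HBL_1 cells, because no repeat culture shows how far cells of 1 line differ.

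In HLY, 12 of 18 B-cell identity genes were under 1 CPM, against 4 in the next line, RCK8, with PAX5, the factor that maintains B-cell fate, at 0.348 CPM (median 744 CPM). A shallow library was excluded, since HLY had 28.4 M counts in genes, above the median. T or NK, myeloid, epithelial or stromal cells under this label were not apparent. Of their 31 markers, 2 reached 10 CPM (CD7 and PECAM1), where the median line had 1 and other lines up to 4. CD3D, LYZ, KRT8 and COL1A1 were under 1 CPM, while GZMA, a T and NK cell marker, was at 8.36 CPM (median 0 CPM). This count cannot exclude these cells, because single markers were raised and CD2, CD8B, GNLY and TRAC were not analysed here. Of the plasma cell genes, 10 of 12 reached 10 CPM in HLY (median over lines 8), with PRDM1 at 501 CPM and SLAMF7 above 1000 CPM. No biological explanation was tested for this pattern.

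Neighbouring genes rose and fell together across lines, with a mean rho of 0.248 for adjacent genes, 0.0934 for genes 20 apart and 0.0557 for genes 100 apart, against 0.000473 for genes on different chromosomes. Reads shared between related or overlapping genes were excluded as the cause only for genes 20 apart, where mean rho was 0.0915 for genes whose symbols start differently. For adjacent genes the same rule gave 0.228, but it does not remove overlapping or antisense partners, so shared reads stay open there. After a fit on GC content and transcript length, the mean rho 20 genes apart stayed 0.0807 above the mean rho of genes on different chromosomes. The fit raised the latter mean from 0.00106 to 0.0293, so it does not show that such bias was removed and cannot exclude it. Gains and losses of chromosome segments that differ between lines could account for the pattern, since the mean rho 100 genes apart stayed 0.0479 above that of different chromosomes after the same fit. DNA copy number was not analysed here, so regulation shared by a region stays open.

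Random orders of each covariate over the lines were tried 29 times, raised from 19 after the first 19 had been seen, because 1 of 20 is not under 0.05. Of 30 orders with the real one included, 1 gave at least as many genes for each covariate. The highest count of a random order was 129 genes for the cell-of-origin axis against 2340, 65 for MYC against 463 and 81 for the MHC class II score against 149. In the first 19 orders these highest counts were 127, 52 and 34. The median random order gave 28 genes for the axis, 20 for MYC and 21 for the class II score, all called without a real relation. Some of the genes called for each covariate may therefore be false calls, which weighs most on the 149 of the class II score.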
